A study of Caenorhabditis elegans with 4 samples.

How the data were processed

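The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for HTP-3, a HORMA-domain protein of the meiotic chromosome axis, from whole young adult Caenorhabditis elegans with a germline. The strain was fem-2(b245); fem-2 acts in sex determination, where it promotes male fates. The labels name 4 samples, which are 2 ChIP libraries and 2 input DNA libraries, numbered as replicates 1 and 2. Per the labels' protocols, frozen and ground worms, grown at 20 °C, were crosslinked for 20 min in EGS and a further 10 min in EGS with formaldehyde, sonicated, and immunoprecipitated with 5 µg of an affinity-purified rabbit polyclonal antibody; single-end indexed libraries were sequenced on Illumina instruments. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

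Each of the 3 files is a list of peak intervals with one score per peak. Per the file headers, coordinates are on the WormBase WS220 build (ce10 in the submitters' processing notes), and per the submitters' processing notes reads were aligned with BWA. Per the source column of the files, the authors called the replicate peaks with MACS, version not given, and the combined list with MACS v2. The scores are the authors' own peak score, deposited per peak, and the scale is not stated; the replicate scores begin at 50.02 and 50.01 and the combined scores at 1.30. Scores were therefore compared only within one list. They served to rank or filter peaks and, in the closing comparison, to set X against autosomes by the median score of bins. The control library, the threshold, read filters and the way in which the combined list was made from the replicates are not given in the sources used here. No processed file of the input libraries was used here, so no ChIP to input comparison was made and the background is known only through the authors' calls. Read depth is not in the peak lists and is unknown; intervals on shares of peaks are 95% Wilson intervals, which cover counting error of peaks only and treat neighbouring peaks as independent.

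Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on the 6 nuclear chromosomes were analysed together, and mitochondrial peaks were set aside. The extent of a chromosome was taken as the largest peak end in any list, because chromosome lengths are not in the headers. Overlap between lists meant at least 1 bp in common, and was compared with 10000 circular shifts of the other list along each chromosome (one-sided). Peak density was measured in 201 bins of about 500 kb, with each peak placed by its midpoint; bin classes were compared by two-sided permutation with 100000 resamples, over all bins for X against autosomes and within chromosomes for centres (the middle part when a chromosome is cut into 3 equal parts) against arms (the outer parts). Ends that carry the meiotic pairing centre (right on I and V, left on II, III, IV and X) were compared with the opposite outer parts by an exact sign-flip permutation test over 6 chromosomes; the assignment fixed beforehand had III at the right end, which was an error, and both versions are given. The median distance between midpoints of neighbouring peaks was compared with 10000 random placements (two-sided). The combined list was the main list, and each replicate list alone served as the analysis without the other replicate, although the lists also differ in the caller named and in the range of scores. An interaction of centre and X, by permutation of residuals within chromosomes, was added after the data were seen. Benjamini-Hochberg adjustment covered these 9 tests, both versions of the pairing centre test included.

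The main tests and alternatives were fixed before the data were examined. Added after seeing the data were the interaction and the pairing centre of III at the left end. So were X against autosomes without V, against autosomal arms only and against autosomal centres only. Rotation of bins or residuals along the chromosome and placement within 500 kb bins were also added then. The same holds for the tests of peaks in the first kb of chromosomes and of the longest stretches without peaks. It also holds for the bootstrap interval of the X centre to arm ratio and the exact permutation of X among the 6 chromosomes. Replicate peaks cut to the replicate 1 median width were a further addition. Peak width in pairs, the centre to arm ratio by replicate support and scores on X were examined as follow-ups. These were set before their own results were seen, but after the patterns that prompted them. They were not among the adjusted tests. Regions to be named were the 10 combined peaks with the highest score that overlapped both replicate lists, and the bin with most combined peaks on each chromosome. Alternatives were the 50% of each list with the highest scores, a reciprocal overlap of 50%, uniform placement, bins of 200 kb and 1 Mb, covered length in place of peak number, other definitions of centres and ends, and merging of peaks under 500 bp apart. Planned comparisons with gene features, gene lists and base composition were not made, since no genome or annotation of the WS220 build was used here and coordinates were not converted between builds; genes are therefore not named. On simulated lists, a planted shared 50% of replicate peaks was recovered as 50.1% over 10 runs, a planted centre to arm ratio of 1.5 as 1.48 and a planted X to autosome ratio of 0.75 as 0.751 over 100 runs each; with nothing planted, 6.0% and 4.0% of the runs of the last pair fell under a p of 0.05. For the interaction, 100 of 100 simulated runs with a centre ratio of 1.5 on autosomes and 1 on X fell under 0.05, and 6.0% with the same ratio on both. Apart from the planted sharing and densities, simulated peaks were placed independently at random with fixed widths. The real peaks lay closer together than random placement gave, so these rates need not hold for the real lists.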

Results

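HTP-3 occupancy was described from 3 peak lists, one for each of the 2 ChIP replicates and a combined list under the name of the whole experiment. The replicate 1 list held 3295 peaks and the replicate 2 list 4007, of which 4006 were nuclear. The mean was 3650 ± 503 nuclear peaks (SD, n = 2). The combined list held 11716 peaks, of which 11713 were nuclear, 3.21 times the replicate mean. The peaks were narrow in the combined list (median 298 bp) and in replicate 1 (median 478 bp), and broad in replicate 2 (median 1455 bp). The shortest peak was 146 bp in the combined list and in replicate 1, and 654 bp in replicate 2. Accordingly, replicate 2 covered 8.18% of the chromosomes (8.20 Mb), replicate 1 covered 2.11% (2.11 Mb) and the combined list 4.98% (4.99 Mb).

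**Figure D1:**
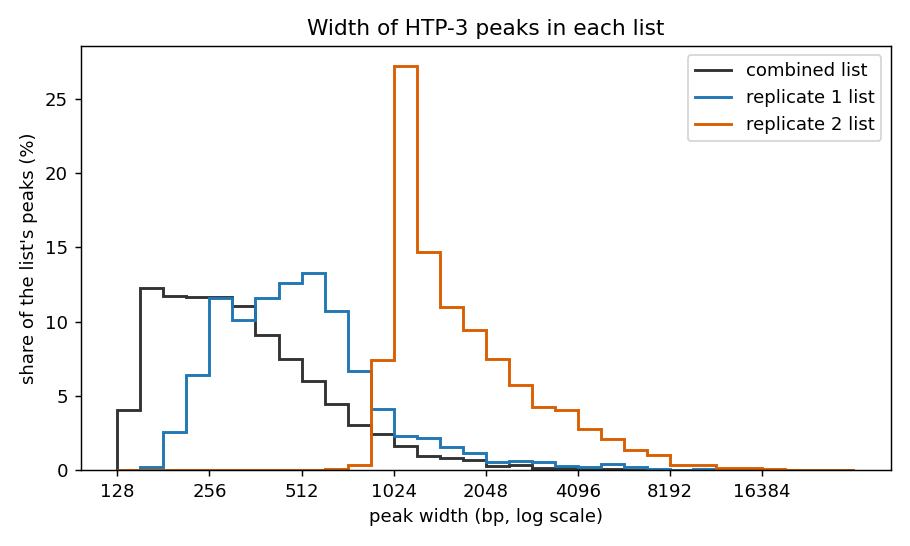
Share of each list's nuclear peaks (%, vertical axis) by peak width (bp, log scale), in equal steps on the log scale, for the combined list and the 2 replicate lists. The replicate 2 distribution lies to the right of the others, with a median of 1455 bp against 478 bp in replicate 1 and 298 bp in the combined list.

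The first comparison asked whether the replicates marked the same regions. Of the replicate 1 peaks, 2881 of 3295 (87.4%, 95% Wilson interval 86.3 to 88.5) overlapped a replicate 2 peak, against 11% on average after circular shifts. In the other direction, 2052 of 4006 replicate 2 peaks (51.2%, interval 49.7 to 52.8) overlapped a replicate 1 peak, against 7.47% after shifts. Both shares exceeded all 10000 shifts (one-sided permutation p = 0.0001, the smallest they can give; adjusted p = 0.00023). With replicate 2 peaks cut to the replicate 1 median width, a setting added after the data were seen, the shares were 53.5% of replicate 1 and 42.4% of replicate 2, both still above all shifts. The replicates shared locations more than boundaries. Only 207 peaks of each list overlapped reciprocally by 50% or more, 6.28% of replicate 1 and 5.17% of replicate 2, still above all shifts. Width limits these shares, since 2 peaks whose widths differ more than 2-fold cannot reach this criterion wherever they lie. In the pairs described below, the lower quartile of the width ratio was already 2.36. Replicate 2 held 490 peaks that each spanned 2 or more replicate 1 peaks, up to 12 in one. Among 1560 pairs in which exactly 1 peak met exactly 1 peak, the midpoints lay a median of 86.5 bp apart and replicate 2 was wider in 1555 pairs, by a median of 3.31 times (quartiles 2.36 and 4.85). Across the 201 bins, peak densities of the replicates had a Pearson r of 0.78 and a Spearman rho of 0.773; bins are not independent replicates. Within chromosomes, the Spearman rho ran from 0.515 on X to 0.836 on III.

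Overlap rose with the score of the peak within its own list. In replicate 2, 17.96% of the lowest-scoring quintile of peaks (144 of 802, interval 15.4 to 20.8) overlapped replicate 1, compared with 95.3% of the highest-scoring quintile (763 of 801, interval 93.6 to 96.5). In replicate 1, the shares were 79.5% (524 of 659, interval 76.3 to 82.4) and 96.4% (635 of 659, interval 94.6 to 97.5). Under the reciprocal criterion the highest-scoring quintiles overlapped in 15.6% and 24.6%. No chance level was computed per quintile, and wider peaks meet the 1 bp criterion more easily. What part of the rise with score comes from peak width was not tested.

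**Figure D2:**
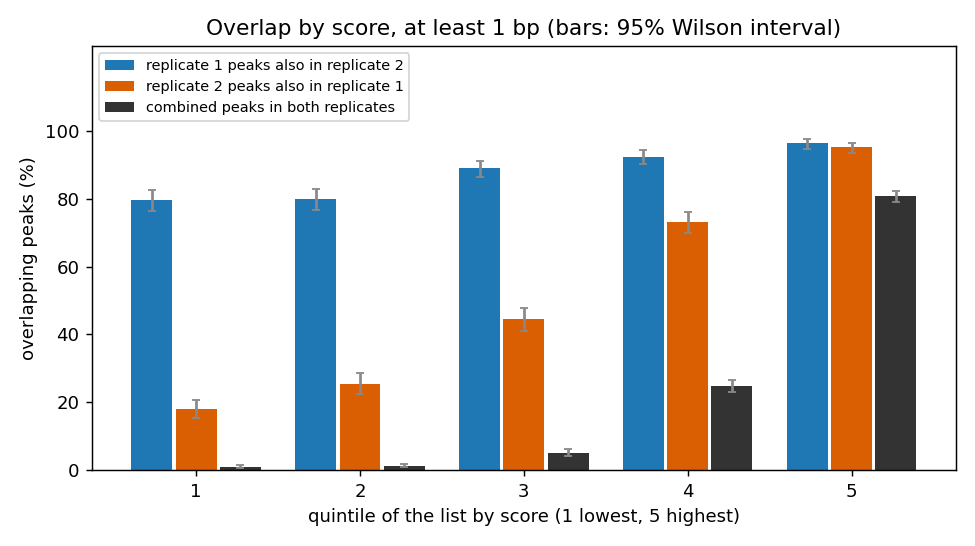
Share of peaks (%, vertical axis) that overlapped by at least 1 bp, by quintile of the list's own score from 1 (lowest) to 5 (highest); blue, replicate 1 peaks in replicate 2; orange, replicate 2 peaks in replicate 1; black, combined peaks in both; error bars, 95% Wilson intervals. The highest quintiles reach 96.4%, 95.3% and 80.8%, and the lowest quintiles 79.5%, 17.96% and 1.07%.

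The combined list contained nearly all replicate peaks and many others. It overlapped 96.8% of the replicate 1 peaks (3189 of 3295) and 98.2% of the replicate 2 peaks (3934 of 4006), with a mean of 1.78 combined peaks per replicate 2 peak. Conversely, 2645 of the 11713 combined peaks (22.6%, interval 21.8 to 23.4) overlapped peaks of both replicates, 4456 (38.0%) only replicate 2, 344 (2.94%) only replicate 1, and 4268 (36.4%, interval 35.6 to 37.3) neither. Peaks found in both replicates had a median combined score of 33.0 and a median width of 606 bp; those found in neither had 5.20 and 212 bp. In the highest-scoring quintile of the combined list 80.8% of peaks (1892 of 2343) were in both replicates, and in the lowest-scoring quintile 1.07% (25 of 2343). This split depended on the overlap criterion and on peak width. With a reciprocal overlap of 50%, which no combined peak under 327 bp (55.9% of them) can reach with the shortest replicate 2 peak of 654 bp, 2.39% of combined peaks were in both, 1.91% in replicate 2 only, 17.5% in replicate 1 only and 78.2% in neither; with replicate peaks cut to the replicate 1 median width, the shares were 15.6%, 19.2%, 9.24% and 56.0%.

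The 10 highest-scoring combined peaks with support in both replicates lay on II (4 peaks), I (2), III (2), IV (1) and X (1), with none on V. No combined peak of as high a score lacked support in a replicate. The highest score, 174.79, belonged to a 665 bp peak near the right end of III (13447964 to 13448628), followed by 174.06 for a 668 bp peak on IV (13881643 to 13882310). The 4 peaks on II were at 5055005 to 5056987, 8460520 to 8461001, 9633755 to 9634720 and 11096816 to 11097911. Those on I were at 2070574 to 2072200 and 7865954 to 7868728, the latter the widest of the 10 at 2775 bp. The remaining peaks were on III at 793442 to 794167 and on X at 2242737 to 2243214, the narrowest of the 10 at 478 bp. Only 3 of the 10 lay in the middle part of their chromosome. In each replicate list these sites also ranked high: at most 6.71% of replicate 1 peaks and 9.74% of replicate 2 peaks scored higher than the peak at the same site. The combined list carries the name of the whole experiment, so these ranks are not independent of how the sites were chosen. All coordinates are WS220; gene features at these sites were not analysed here.

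The chromosomes carried peaks at different densities. III was the densest in the combined list, with 160 peaks per Mb (2205 peaks), followed by I with 145.7, II with 120.2 and IV with 115.9. X had 93.9 peaks per Mb (1663 peaks) and V the fewest, 85.5 (1788 peaks). In the replicate lists, III averaged 49.0 ± 4.0 peaks per Mb (SD, n = 2), I 44.0 ± 8.77, II 37.5 ± 5.23, IV 36.7 ± 4.25, X 30.3 ± 6.95 and V 26.8 ± 1.83. Relative to all chromosomes, which removes the difference in list length, III was at 1.35 ± 0.076 and V at 0.739 ± 0.052.

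X was compared with the autosomes because X, unlike the autosomes, is kept largely silent for much of germline development in C. elegans. X bins held 93.9 ± 25.9 combined peaks per Mb (SD, 35 bins) and autosomal bins 121.8 ± 55.9 (SD, 166 bins), a ratio of 0.771 (two-sided permutation p = 0.0042, adjusted p = 0.0063). The ratio was 0.797 ± 0.087 over the replicate lists (SD, n = 2): 0.736 in replicate 1 (permutation p = 0.003) and 0.859 in replicate 2, where the difference did not pass the test (permutation p = 0.11). X was not the sparsest chromosome in the combined list or in replicate 2, since V was sparser, while in replicate 1 X and V had 25.4 and 25.5 peaks per Mb; with the chromosome as the unit, an exact two-sided permutation of 1 X among 6 chromosomes gave p = 0.50 in the combined list, 0.33 in replicate 1 and 0.67 in replicate 2, where the smallest possible is 0.17. Set against autosomal arms alone, which had 101.7 ± 49.7 peaks per Mb (SD, 110 bins), X gave a difference that did not pass the test (ratio 0.923, permutation p = 0.37). Set against autosomal centres, with 161.5 ± 45.4 (SD, 56 bins), its ratio was 0.581 (permutation p = 1e-05, the smallest that the resamples can give).

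The autosomes were denser in their centres than on their arms. The centre to arm ratio was 1.59 in the combined list (two-sided permutation within chromosomes, p = 1e-05, the smallest possible; adjusted p = 9e-05) and 1.59 ± 0.078 over the replicate lists (SD, n = 2). All 5 autosomes had the denser centre in each of the 3 lists. In the combined list the ratio was 1.74 on II, 1.74 on V, 1.59 on I, 1.47 on IV and 1.43 on III. The arms of an autosome were not alike: the left part of II held 62.9 peaks per Mb and its right part 131.0, while the right part of III held 155.4 and its left part 123.8. On X, centre and arms had 92.1 ± 16.42 (SD, 11 bins) and 94.7 ± 29.5 (SD, 24 bins) peaks per Mb, a ratio of 0.973 with a bootstrap 95% interval of 0.829 to 1.14 (permutation p = 0.79, adjusted p = 0.79). The centre effect was larger on autosomes than on X by 0.524 of the chromosome's mean density (permutation of residuals, p = 8e-05, adjusted p = 0.00023), and by 0.555 in replicate 1 (permutation p = 0.00094) and 0.603 in replicate 2 (permutation p = 7e-05). When bins were rotated along the chromosome, which keeps neighbouring bins together, the autosomal p was 0.00081 and that of the difference between autosomes and X 0.019. The contrast rests on 1 X chromosome, at 0.973 against 1.59 ± 0.143 on the autosomes (SD, n = 5); with the chromosome as the unit, an exact two-sided permutation gave p = 0.17 in each list, the smallest that 6 chromosomes allow.

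**Figure D3:**
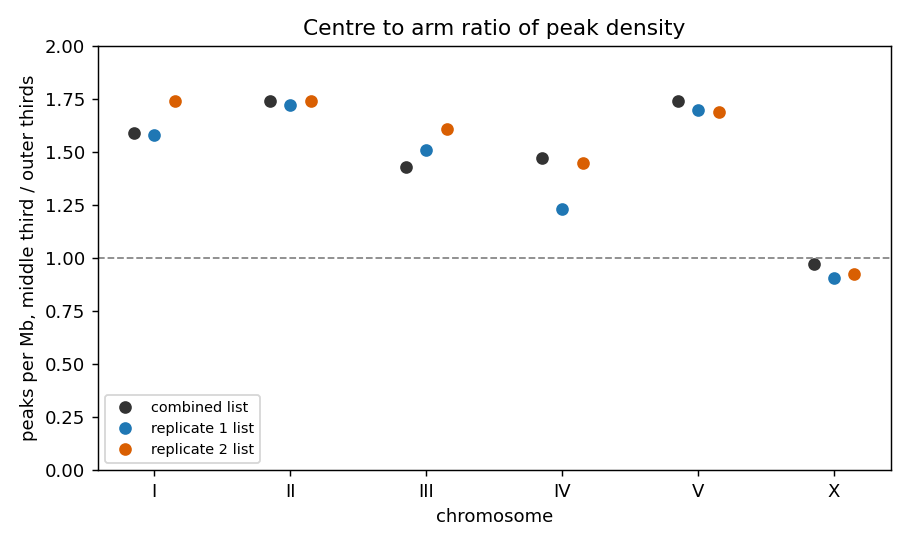
Peaks per Mb of bins in the middle part of each chromosome divided by that of bins in the outer parts (vertical axis), for the combined and the 2 replicate lists; the dashed line marks a ratio of 1. The 5 autosomes lie above 1 in all 3 lists, from 1.23 to 1.74, and X lies between 0.906 and 0.973.

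The bin with the most combined peaks lay in the middle part of I, II, III and IV and outside it on V and X. On III it spanned 6891774 to 7384043 with 136 peaks (276 per Mb, against a median bin of 163), and on I 9043441 to 9545853 with 133 peaks (265 per Mb, median 154). On II it spanned 8869247 to 9361982 with 107 peaks, on V 5972552 to 6470264 with 98 and on IV 8487499 to 8986763 with 97. On X it spanned 4049039 to 4555167 with 78 peaks. These bins ranked first in their chromosome in replicate 2 as well, except on IV, where the bin ranked 3; in replicate 1 they ranked between 2 and 6.

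**Figure D4:**
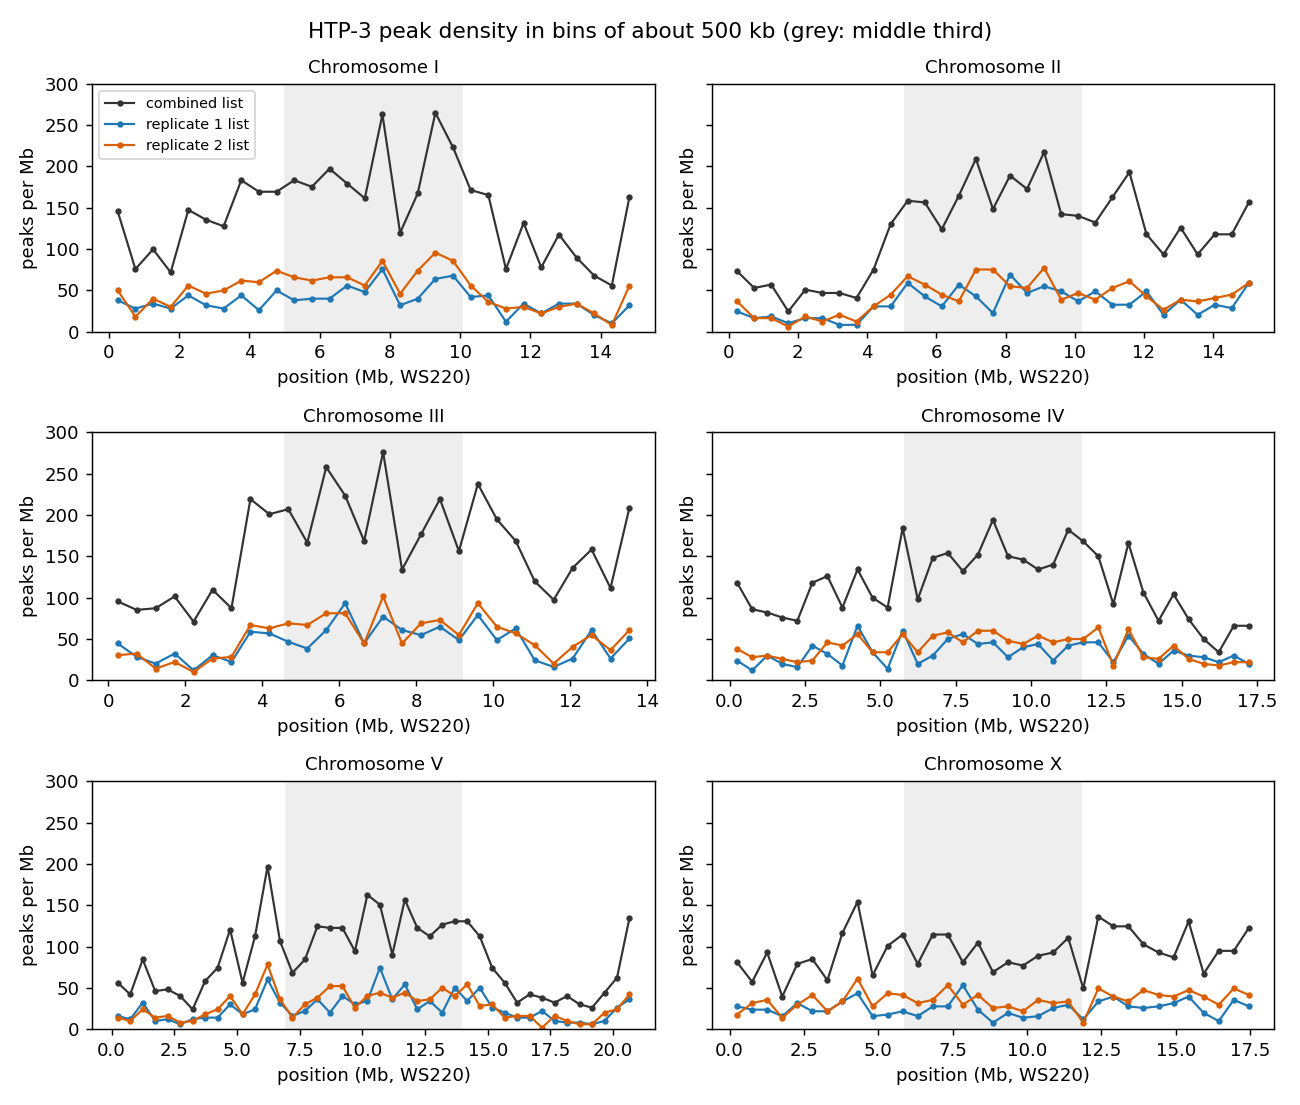
Peaks per Mb (vertical axis) in bins of about 500 kb along the 6 chromosomes (Mb, WS220) for the combined list (black), replicate 1 (blue) and replicate 2 (orange), with the middle part of each chromosome in grey. The combined list peaks at 276 per Mb on III, and on X the curve shows no rise in the grey part (92.1 in the centre against 94.7 on the arms).

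Chromosome ends that carry the meiotic pairing centre, the sites through which homologous chromosomes pair and synapse in C. elegans, were compared with the opposite ends. The pairing centre ends held 91.9 ± 26.2 combined peaks per Mb (SD, n = 6 chromosomes) and the opposite ends 115.0 ± 29.5, a ratio of 0.799 that did not pass the test (exact sign-flip permutation test, two-sided p = 0.062, adjusted p = 0.08; the smallest p that 6 chromosomes allow is 0.03125). The pairing centre end was sparser on II (ratio 0.48), III (0.797), V (0.802), X (0.84) and I (0.842) and denser on IV (1.15). In replicate 1 it was sparser on all 6 chromosomes (ratio of mean densities 0.817, exact p = 0.031, the smallest possible), with 0.995 on IV, and in replicate 2 on 5 of 6 (0.743, exact p = 0.062). The assignment fixed beforehand, with III at the right end in error, gave a ratio of 0.885 (exact p = 0.44, adjusted p = 0.49).

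Peaks lay closer together than random placement gave. Neighbouring combined peaks had midpoints a median of 2.40 kb apart, against 5.74 kb for random placement within chromosomes (ratio 0.417, two-sided permutation p = 0.0002 over 10000 placements, the smallest they can give; adjusted p = 0.00036). The distances were 9.21 kb against 20.5 kb in replicate 1 (ratio 0.45) and 11.5 kb against 16.8 kb in replicate 2 (ratio 0.682). Random placement within each 500 kb bin, which keeps the uneven density along chromosomes, gave 5.25 kb (ratio 0.457, permutation p = 0.0002). With combined peaks under 500 bp apart merged into 8775 regions, the median was 4.73 kb against 7.73 kb (ratio 0.612).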

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

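The tests of a chromosome's first kb and the interaction of centre and X with its rotation were chosen after peak positions or densities were seen. So were the tests of X among the 6 chromosomes and the interval of the X ratio. The other tests here were set before their results were seen, but after the patterns they address.

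The mitochondrial genome, which entered no comparison, carried called peaks. Replicate 2 had 1 mitochondrial peak, which covered 13484 bp with a score of 176.52, and 46.6% of the replicate 2 peaks scored higher. The combined list had 3 mitochondrial peaks, of 6614, 3635 and 2137 bp, and replicate 1 had none.

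Replicate 2 peaks were wider than replicate 1 peaks. Fusion of neighbouring called replicate 1 peaks is not enough as the cause. In pairs of exactly 1 peak each, the median width ratio was still 3.31. Such pairs leave out any second called replicate 1 peak, so merging with signal not called in replicate 1 was not tested. A fixed extension of each peak by the peak caller stays open: the median width difference changed little between peaks of low and high replicate 1 score (ratio 0.771, highest to lowest quintile), and the extra length was similar on the left (408 bp) and the right (421 bp). The quartiles of the difference, 708 and 1634 bp, show that no single length accounts for every pair. The labels give no biological difference between the replicates, so no biological explanation was tested.

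Autosomal centres held more peaks than arms, and X did not show the difference. Weak calls held only by the combined list are argued against as the cause. Peaks in both replicates had a centre to arm ratio of 1.69, above the 1.59 of the whole list, and peaks in neither had 1.21. A few dense bins are not the cause either, since the ratio of bin medians was 1.67. Chance scatter of bins is argued against by the interaction (permutation p = 8e-05, and 0.019 with residuals rotated along the chromosome). That test was prompted by the ratios it tests. The bootstrap upper bound of the X ratio, 1.14, lies under the autosomal 1.59, which goes against low precision on X only in part. The bootstrap treats neighbouring bins as independent, so its interval may be too narrow. In replicate 1 the bound was 1.23, under the autosomal 1.54 but equal to the ratio of IV alone. With the chromosome as the unit, X had a ratio of 0.973 and the autosomes 1.43 to 1.74, and an exact permutation test of 6 chromosomes cannot give a p below 0.17. Gene density, repeats that limit unique alignment on autosomal arms, input signal and axis organisation stay open and untested, since no annotation of the build and no input values were used here.

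Peaks lay within the first 1 kb of several chromosomes, in the replicate lists more than random placement gave. Replicate 1 had such peaks on I, II, III, IV and X, 5 of 6 left ends (random mean 0.335, permutation p = 0.0001, the smallest that 10000 placements give), and replicate 2 on I, IV, V and X, 4 of 6 (random mean 0.725, permutation p = 0.0019). In the combined list they were on I, V and X, 3 of 6, a number that random placement reached in a share of 0.055 of the draws. Peaks were also placed within the first 500 kb bin of each chromosome, which keeps the density there. The permutation p was then 0.0001 in replicate 1, 0.0006 in replicate 2 and 0.024 in the combined list. In the combined list, 41.2% of peaks scored higher than the peak on I, 95.5% than that on X and 99.4% than that on V. The count in that list therefore includes low-scoring calls. The share scoring higher ran from 29.5% (I) to 80.4% (IV) in replicate 1. In replicate 2 it ran from 25.4% (I) to 96.6% (IV). Reads of end repeats that gather at the ends of the assembly could produce such peaks, as could occupancy at chromosome ends; neither was tested, and right ends were not examined because chromosome lengths were not used.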

How the results depend on the processing

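Of 62 recomputed values, 52 kept their direction and side of the threshold or stayed within their error, 5 moved, 2 fell short of the threshold, 1 passed it and 2 changed direction. The 52 do not all have a stable size. They include the replicate overlaps, which fell to 6.28% and 5.17% with reciprocal overlap of 50% but stayed above all shifts. They also include results that passed the threshold in neither setting. A further 22, of peak number, width and relative chromosome density, are not counted, since their spread comes from the same 2 replicate lists. The values without a replicate come from the other replicate's own list, called separately with MACS of a version not given, so the caller named, the range of scores and the list length changed together with the replicate. The autosomal centre to arm ratio stayed between 1.49 and 1.74, the interaction of centre and X between 0.501 and 0.603, and the neighbour distance ratio between 0.417 and 0.682, all past the threshold under each alternative run. The X to autosome ratio was not called in the replicate 2 list (0.859, permutation p = 0.11; 0.736 in the replicate 1 list) and ran from 0.712 to 0.835 under the other settings fixed beforehand. In 3 alternatives added after seeing the data, which changed the reference set, it was 0.923 against autosomal arms only (permutation p = 0.37, not called), 0.581 against autosomal centres only and 0.70 without V. The X centre to arm ratio turned to 1.01 with the centre as the middle 50% (permutation p = 0.92), and the ratio for pairing centre ends, with III at the right end, to 1.07 in the outermost 1 Mb (exact p = 0.81); neither was called under any setting, and the cause was not tested. With III at the left end, a correction made after seeing the data, that ratio ran from 0.733 to 0.842 (0.799 in the main setting, exact p = 0.062) and passed the threshold only in the replicate 1 list (0.817, exact p = 0.031; 0.743 in the replicate 2 list). The share of combined peaks in both replicates moved to 2.39% with reciprocal overlap of 50%, and to 15.6% when replicate peaks were cut to the replicate 1 median width, an alternative added later. Width limits the first of these: with the shortest replicate 2 peak at 654 bp, the 55.9% of combined peaks under 327 bp cannot pass. That trimming gave overlaps of 53.5% for replicate 1 and 42.4% for replicate 2, still above all shifts. In the replicate lists, the number of nuclear peaks ran from 3295 to 4006 and the median width from 478 to 1455 bp, against 11713 and 298 bp in the combined list; what part of this comes from the replicate and what from the caller was not tested. Replicate overlap cannot be recomputed without a replicate. No paired analysis was possible because no values of the input libraries were used here, so the ChIP and input groups that share replicate numbers were not compared. The planned analyses of gene features, gene lists and base composition were not run. Read depth is unknown, so how far it sets the difference in peak number or width cannot be stated.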

Other observations

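The regions in this paragraph and the test of them were chosen after their values were seen. The test of scores on X was set before its result was seen, but after the lower peak density of X. The widest combined peaks were found in both replicates and lay on X at 16929266 to 16943484 (14219 bp), on II at 10541727 to 10554319 (12593 bp) and on III at 3863851 to 3872829 (8979 bp). The region on II was also the widest in each replicate, with 11362 bp in replicate 1 and 22600 bp in replicate 2. Not all wide replicate peaks were shared. The next widest of replicate 1, on I (11076 bp) and V (8164 bp), overlapped no replicate 2 peak. In replicate 2 the next widest, on I (18274 bp), overlapped no replicate 1 peak, while the one after it, on III (17951 bp), did. The longest stretches without a combined peak lay towards chromosome ends: 214 kb on V from 19194315 to 19407852, 170 kb on X from 1627713 to 1797594, and 169 kb on IV from 16676174 to 16845310. Sparse outer parts alone favour long stretches on V and IV. On X the outer parts together were not sparser than the centre (94.7 against 92.1 peaks per Mb). Against 10000 random placements within 500 kb bins, which keep the broad density, a stretch as long had a permutation p of 0.0066 on X, 0.02 on IV and 0.054 on V, and for the longest stretches of the other chromosomes 0.0015 on III, 0.0072 on I and 0.37 on II, without adjustment for the 6 chromosomes. Each of the 3 stretches held 1 replicate 1 peak, and those on X and IV also 1 replicate 2 peak.

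X carried fewer peaks per Mb, and the hypothesis was tested that its peaks also had lower scores. The result went the other way: the mean over bins of the median score was 9.41 on X and 8.03 on autosomes in the combined list (ratio 1.17, permutation p = 0.00044) and 236.3 against 187.3 in replicate 1 (ratio 1.26, permutation p = 0.012). In replicate 2 the difference did not pass the test (175.5 against 171.8, ratio 1.02, permutation p = 0.80). The single-library lists therefore differ on this point, and whether they differ beyond chance was not tested. The scale of the scores is not stated, so the ratios give a direction and no fold change. These permutations take bins as the unit and rest on 1 X chromosome. With the chromosome as the unit, the smallest possible p is 0.17. The median score of a chromosome was 8.58 on X and at most 7.99 on an autosome in the combined list. In replicate 1 these were 199.9 and 179.1. In replicate 2, X at 157.7 lay within the autosomal 145.8 to 168.0.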
